A study of Drosophila melanogaster with 4 samples.

How the data were processed

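H3K4me2 ChIP-seq was carried out on nuclei of wild-type Oregon-R larvae at the third instar, with 2 immunoprecipitates and 2 inputs. Per the labels' protocols, homogenised tissue was crosslinked with formaldehyde, chromatin was released by SDS lysis and sonication, and it was precipitated with the antibody, named in the labels as an Active Motif product. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Each input served the immunoprecipitate of the same replicate number, per the labels. No file of the inputs was used here, so they enter only through the calls that the authors made against them.

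The data were 3 lists of regions, 1 for each immunoprecipitate and 1 for the combined replicates, in GFF3 format. Per the file headers, coordinates follow FlyBase release 5. The lists call their entries regions of significant enrichment or depletion, and the deposited score of each region is a single number whose scale and log base the files do not state. Scores were used to rank and filter regions within a list, and over matched regions they were compared by Spearman's rho and Pearson's r. The ranking by the mean score of both replicates, and the limit of 1 in the closing section, take the 2 replicate lists to share a scale, which is not stated. The region caller, its threshold, its length limits and the way the replicates were combined are not given in the sources used here. The lists hold no read counts, so depth is unknown, no interval from read counts can be given, and a difference between lists may partly follow from depth. Coordinates were read as GFF3 gives them, from 1 with both ends included. A single region of replicate 2 starts at 0. Regions within a list did not overlap each other. Depleted regions were left out of all other values. The deposited combined list was treated as a pooled value with no error or n.

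Covered shares were computed from the sequence lengths in the file headers, for each sequence, for windows of 1 Mb, and for the 1 Mb at the centromeric end of each long arm. Mean and SD are over 2 replicates. Regions were called overlapping when they shared at least 1 bp. Overlap between replicates was tested by shifting the regions of replicate 1 circularly within each sequence, 1000 times with a fixed seed, which keeps their lengths and spacing. Checked on simulated lists of 4682 regions with the lengths of replicate 1 on the arms, the code gave an overlap of 31.8% when no region was shared (shifted mean 32.7%, permutation p = 0.7), and of 90.2% when 89.8% were copied (permutation p = 0.0099, the smallest that the 100 shifts used there can give). Score agreement was taken over regions that overlapped exactly one region in each direction, with a 95% interval from 1000 bootstrap draws of pairs. Intervals of shares are exact binomial 95% intervals. They cover counting error only and treat neighbouring regions as independent. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

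The rule for named regions, the tests of overlap and score agreement, and the alternatives named next were fixed before the data were examined. The rule took the 10 longest regions present in both replicates, the 10 with the highest mean score, and the 3 highest-scoring regions of each replicate without a counterpart. Alternatives were other overlap limits (50% of the region, 50% reciprocally), the 50% of regions with the higher score, a length limit of 500 bp, joining regions under 500 bp apart, restriction to the 6 arms, a limit of 3 kb for broad regions, the combined list in place of the replicates, and leaving out each replicate. The alternatives of score agreement on only the 6 arms and of combined regions no shorter than the shortest replicate region were added after the lists had been seen. So were all tests among the other observations at the end, and the test of the long arms over windows. The latter used 100000 permutations and Benjamini-Hochberg adjustment over the 5 arms. The test of weak enrichment replaced an earlier one, the share of regions in the lowest 25% of scores, which did not separate the sets compared. The replacement was first run only on regions no shorter than the shortest replicate region, and the comparison over all regions was added after that result was seen. Windows, centromeric ends, unmarked stretches and the share of regions above the median score were also added then. The plan also held 5 results that need gene positions (promoter share, genomic features, position around transcription start sites, 20 gene lists, and marked genes on X and chromosome 4). They were not run, because the gene table at hand follows release 6 and no coordinates were converted between releases. Regions are therefore given by position only, without gene, exon or intron.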

Results

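Chromatin carrying histone H3 dimethylated at lysine 4 (H3K4me2) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei of wild-type Oregon-R Drosophila melanogaster larvae at the third instar, the last larval stage before the animal forms a pupa. H3K4me2 is a histone mark found around the promoters and enhancers of genes that are active or poised for activity. The series held 4 samples, namely 2 replicates of the H3K4me2 immunoprecipitate and 2 replicates of sonicated input chromatin, which is chromatin sequenced without selection by an antibody. Each immunoprecipitate had a list of regions enriched over the input of the same replicate number, and a further list combined the replicates. Replicate 1 had 4752 enriched regions covering 21.2 Mb, and replicate 2 had 4701 covering 20.7 Mb. The combined list had 4991 enriched regions covering 22.9 Mb. Read totals were not used here, so the sequencing depth behind each list is unknown. The scores attached to the regions were the authors' own, on a scale that the sources used here do not state. Nothing in the labels says whether the replicates came from separate collections of larvae, so the spread between them may be technical.

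The first comparison, between chromosome arms, asks where the mark lay, using the regions that the authors called against input. H3K4me2 regions covered 17.2% ± 0.277 (SD, n = 2) of the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X) in the FlyBase release 5 assembly. Chromosome arm 2R was the most densely marked, with 19.9% ± 0.380 of its 21.1 Mb covered and 45.8 ± 0.033 regions per Mb (SD, n = 2). The other long arms had 17.7% ± 0.169 (X), 17.6% ± 0.334 (3R), 15.9% ± 0.290 (3L) and 15.3% ± 0.250 (2L) of their sequence covered (SD, n = 2). Chromosome 4, a small chromosome that is packaged largely as heterochromatin and yet carries active genes, had 14.8% ± 0.526 covered (SD, n = 2), close to 2L. The assembled heterochromatin scaffolds of chromosomes 2, 3, X and Y, 9.28 Mb in all, had 1.44% ± 0.0043 covered (SD, n = 2). Over complete windows of 1 Mb, in a test added after the lists had been seen, 2R had a mean of 20.1% covered in 21 windows against 16.8% in the 96 of the other long arms (two-sided permutation p = 0.023, adjusted for the 5 long arms p = 0.12). The adjusted p of the other long arms was 0.16 (2L), 0.46 (3L), 0.73 (X) and 0.83 (3R), so no long arm passed 0.05. Chromosome 4 and the scaffolds were not tested. Covered shares also depend on how much of each sequence can be aligned uniquely, which was not measured.

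Chromosome 4 was marked over about as much of its sequence as 2L, and fewer of its regions scored above their list's median, most clearly in replicate 1. On chromosome 4, 10 of 57 regions in replicate 1 (17.5%, exact 95% interval 8.75 to 29.9) and 21 of 58 in replicate 2 (36.2%, 24.0 to 49.9) scored above their list's median. On 2L, 2R, 3L and 3R together the share was 50.1% in replicate 1 and 49.6% in replicate 2, and the latter lies inside the interval of chromosome 4 in that replicate. No test was run on this difference. The share was 20.0% ± 1.79 on the heterochromatin scaffolds and 54.1% ± 0.487 on X (SD, n = 2). When only regions scoring above the list's median were counted, the covered share of chromosome 4 was 2.99% in replicate 1 and 6.18% in replicate 2, with a mean of 4.58%, against 11.3% for the 6 arms under the same limit. Regions on chromosome 4 were also short, with a median length of 2737 bp in replicate 1 and 2774 bp in replicate 2. Scores rose with length across regions, so length and score are mixed in the comparison of chromosome 4. X regions had a median length of 3822 bp in replicate 1 and 3779 bp in replicate 2, against 3341 bp and 3353 bp on 2L, 2R, 3L and 3R. The share of regions of 5 kb or more was 34.7% ± 0.497 on X and 26.5% ± 0.582 on those autosomal arms (SD, n = 2). Intervals on shares of regions cover counting error only.

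Coverage varied widely along each of the 5 long arms, and the pattern was nearly identical in both libraries. Over the 118 complete windows of 1 Mb on the arms, the covered share ranged from 2.45% to 30.0%, with a median of 17.2%, and the replicates never differed by more than 1.77 percentage points in a window. The most densely marked windows were 3R 5000001 to 6000000 at 30.0% ± 0.378, 2R 3000001 to 4000000 at 29.4% ± 1.25 and 2R 19000001 to 20000000 at 28.4% ± 0.432 (SD, n = 2). The least marked were 3L 23000001 to 24000000 at 2.45% ± 0.0201, 2L 14000001 to 15000000 at 3.89% ± 0.0705 and 2L 17000001 to 18000000 at 4.15% ± 0.0968 (SD, n = 2). The 1 Mb at the centromeric end of the assembled arm was sparsely marked on 4 of the 5 long arms. It was covered to 1.60% on 3L against 16.5% over the rest of that arm, to 5.27% on 2R against 20.7%, to 6.65% on X against 18.3%, and to 6.91% on 2L against 15.7%. The exception was 3R, with 16.9% ± 0.411 covered at this end and 17.6% ± 0.331 elsewhere (SD, n = 2). Heterochromatin scaffolds are separate sequences in this assembly, so how far each end lies from the centromere is not known here.

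**Figure D1:**
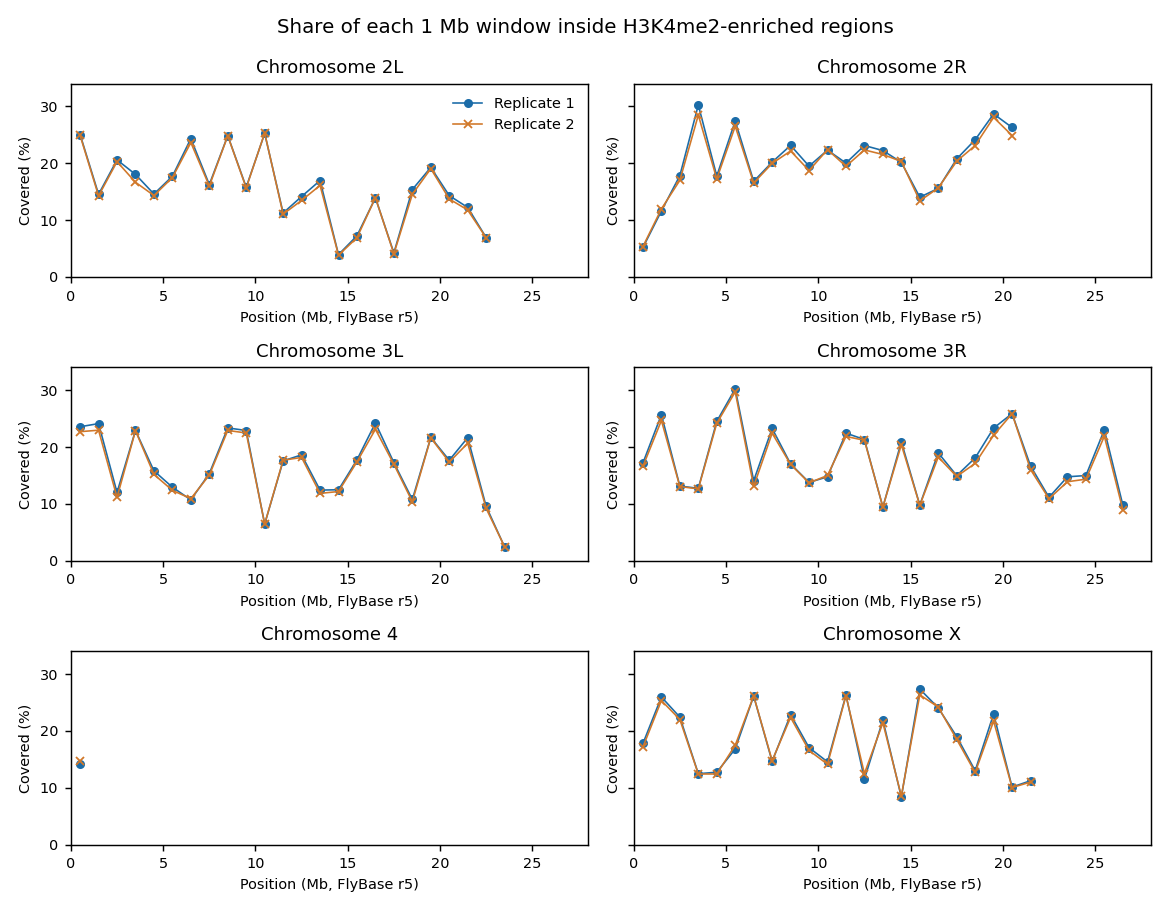
Share (percent) of each complete 1 Mb window lying inside enriched regions, against position (Mb) on each chromosome arm; circles are replicate 1 and crosses replicate 2. The 2 replicates overlie each other, with values from 2.45% to 30.0% and low windows near the centromeric ends of 2L, 2R and 3L.

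Long stretches of the arms held no enriched region in either replicate. The longest lay on 2L from 15771978 to 16249548 (478 kb), followed by 2L from 16911301 to 17381802 (471 kb), X from 20530666 to 20897671 (367 kb), X from 21501682 to 21845637 (344 kb) and 3R from 23815211 to 24149296 (334 kb). The combined list placed 2, 0, 2, 2 and 1 regions in these stretches, in the same order. Most gaps between neighbouring regions were far shorter. Over all gaps on the arms, the long stretches included, the median was 7.07 ± 0.125 kb, and 7.27% ± 0.520 of gaps were under 500 bp (SD, n = 2).

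As called, most H3K4me2 regions spanned several kb. No region of either replicate list was shorter than 1301 bp. The length limits of the region caller are not known, so the lengths may partly follow from the calling. The median length was 3378 bp in replicate 1 and 3382 bp in replicate 2, with the middle 50% of regions between 2535 and 5304 bp and between 2541 and 5209 bp. Regions of 5 kb or more numbered 1321 in replicate 1 and 1270 in replicate 2, and they held 51.7% and 50.3% of the marked sequence. Of the 1321 in replicate 1, 1199 (90.8%, exact 95% interval 89.1 to 92.3) overlapped a region of 5 kb or more in replicate 2. In the opposite direction, 1207 of 1270 (95.04%, 93.7 to 96.2) did so. The 10 longest regions present in both replicates, ranked by the shorter of the 2 lengths, included 4 on 3R and 4 on X. The longest spanned 3R 7033787 to 7065297 in replicate 1 (31.5 kb) and 7033739 to 7071863 in replicate 2 (38.1 kb). The next were 2R 10038235 to 10064534 (26.3 kb in each replicate), X 1751333 to 1776757 (25.4 and 27.9 kb) and 3L 19886314 to 19911704 (25.4 kb in each). The remaining 6 were 3R 11165430 to 11190440, X 508210 to 532929, 3R 25863555 to 25887116, X 8779414 to 8803165, 3R 5578740 to 5600711 and X 8032348 to 8053434, with lengths of 21.1 to 25.01 kb in replicate 1, whose coordinates these are. These domains were not assigned to genes, because the gene table at hand follows another genome release.

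The regions with the highest scores were not those of the longest domains, which had been picked by length. Ranked by the mean score of both replicates, the first was 3L 1773195 to 1779060 (5.87 kb), with scores of 2.78 and 2.49. It was followed by 3R 27568284 to 27576015 (2.78 and 2.47), 3R 21875991 to 21886882 (2.67 and 2.51), 2R 3559985 to 3564722 (2.76 and 2.43) and 2L 2763888 to 2772092 (2.74 and 2.42). The other regions among the first 10 were X 18271887 to 18280135, U 7541924 to 7544810, 3L 19796221 to 19802705, 3R 17846604 to 17855535 and 2L 9935866 to 9941110, with mean scores from 2.56 to 2.58. U collects sequence that had not been placed on a chromosome. Except for the U region, of 2.89 kb, these 10 regions were 4.74 to 10.9 kb long in replicate 1. The median length of all regions in that list was 3378 bp. Longer regions had higher scores, with a Spearman rho of 0.72 in each replicate. This is a correlation across regions of one library, which are not independent replicates.

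The second comparison, between the replicates, asks how far the 2 immunoprecipitates marked the same sequence. They shared 19.9 Mb, which was 91.1% of all sequence marked in either. When the regions of replicate 1 were moved by a random circular shift along each sequence, keeping their lengths and spacing, the share averaged 9.44% and reached at most 16.8% in 1000 shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the regions in replicate 1, 4539 of 4752 (95.5%, exact 95% interval 94.9 to 96.1) overlapped a region of replicate 2, against 29.4% on average after shifting. Of those in replicate 2, 4572 of 4701 (97.3%, 96.7 to 97.7) overlapped a region of replicate 1, against 29.8% after shifting (one-sided permutation p = 0.001 for both, the smallest possible). Random shifts ignore where regions can lie, so passing them is a low bar for 2 immunoprecipitates with one antibody.

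Regions matched one-to-one were placed and ranked alike. There were 4195 such pairs. Their edges differed by a median of 64 bp, and by up to 321 bp for 90% of edges. None had identical coordinates or scores, so neither list was a copy of the other. Scores in the 2 replicates had a Spearman rho of 0.975 (bootstrap 95% interval 0.973 to 0.977) and a Pearson r of 0.976 across these regions, which are not independent of each other.

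**Figure D2:**
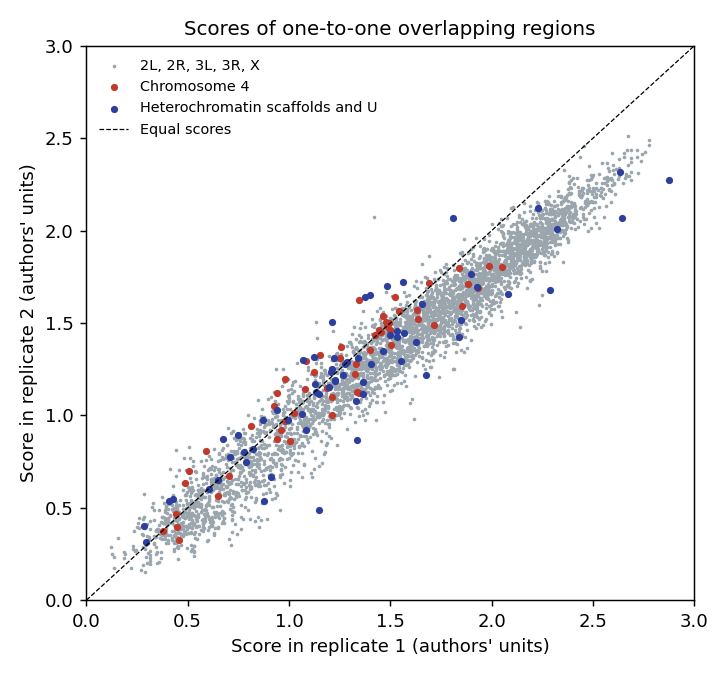
Score of each one-to-one overlapping region (authors' units) in replicate 1 against replicate 2, coloured by chromosome group; the dashed line marks equal scores. The 4195 pairs follow one band (Spearman rho 0.975), and 42 of the 54 pairs on chromosome 4 ranked higher in replicate 2 than in replicate 1.

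Regions found in a single replicate were mostly short and weakly scored, but the highest score of each replicate list belonged to one of them. The 213 regions of replicate 1 without a counterpart had a median length of 1598 bp and a median score of 0.44, against 3535 bp and 1.60 for regions with one. The 129 such regions of replicate 2 had medians of 1565 bp and 0.41, against 3458 bp and 1.45. The 3 with the highest scores in replicate 1 were 3L 13567805 to 13569235 (2.87), U 6666925 to 6668237 (1.18) and 2R 9296063 to 9298048 (0.82). In replicate 2 they were U 7869604 to 7871607 (3.44), U 7531200 to 7533155 (1.81) and 2LHet 254010 to 255642 (0.79). The combined list also contained these 6 regions. The 2.87 of the 3L region was the maximum of replicate 1, where a region on U (7541924 to 7544810) had the same score to all printed digits, and the 3.44 of the U region was that of replicate 2. The combined region over the latter, U 7869528 to 7871582, had the highest score of the combined list, 4.28.

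The third comparison set the combined list against its replicates. It contained nearly everything found in either one, and more. All but 4 regions of replicate 1 and 1 region of replicate 2 overlapped it. Of its 4991 enriched regions, 4349 (87.1%, exact 95% interval 86.2 to 88.1) overlapped regions of both replicates, 195 overlapped replicate 1 only and 124 replicate 2 only. A further 323 (6.47%, 5.80 to 7.19) overlapped neither. Measured in bases, 87.0% of the combined list lay in both replicates, 8.03% in a single replicate and 4.97% in neither. Regions present in both replicates had a median length of 3857 bp and a median score of 1.47. Those in neither had medians of 1260 bp and 0.32, and those in a single replicate 1703 bp and 0.30. The shortest region was 1001 bp in the combined list and 1301 bp in each replicate list.

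**Figure D3:**
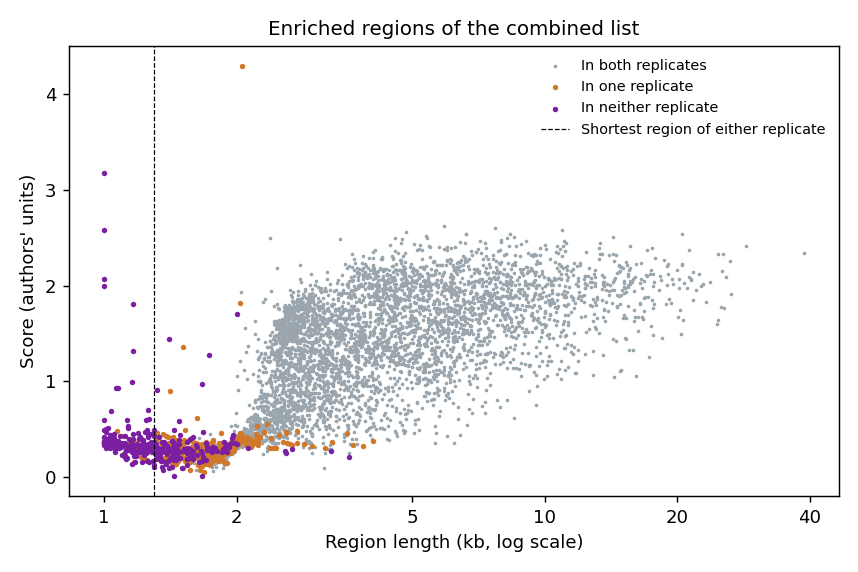
Length (kb, log axis) against score (authors' units) of the 4991 enriched regions of the combined list, coloured by whether they overlap both replicates, a single replicate or neither; the dashed line marks the shortest replicate region, 1301 bp. Regions outside both replicates gather at the short, low-scoring corner, with a few short regions at high scores.

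The combined list also named 3 regions of significant depletion, the only ones in the 3 lists. They lay at 2R 1523171 to 1524841, 3L 15677408 to 15678974 and 3L 20315400 to 20316971, were 1671, 1567 and 1572 bp long, and overlapped no enriched region of either replicate. Their scores were -0.088, -0.00090 and -0.131.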

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

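The overlap between replicates stayed above the shifted lists under each of its alternatives, with 86.2% to 91.2% of marked sequence shared (one-sided permutation p = 0.001 throughout, the smallest possible). Shifted lists are a low bar for 2 immunoprecipitates with one antibody, so this p tells little about the processing. The limit of 500 bp removed no region and so tests nothing. The rank agreement of scores stayed between 0.975 and 0.976 under its 2 alternatives, of which restriction to the 6 arms was chosen after seeing the data. The share of combined regions found in both replicates (87.1%) was 86.6% with 50% of the region overlapped. Without one of the replicates the share found in the other was 89.6% to 91.0%, and it was 90.9% among combined regions no shorter than the shortest replicate region, a limit added after seeing the data, which leaves out short regions by construction. The covered share of the 6 arms (17.2%) was 17.0% and 17.4% for the single replicates, 18.9% in the combined list, and 11.3% with only the 50% of regions scoring higher, which count less sequence by construction. Chromosome 4 went from 14.8% to 4.58% under that limit, as the mean of 2.99% in replicate 1 and 6.18% in replicate 2. Counts of broad regions depend on the limit: at 3 kb they were 2745 and 2723, with 2589 of replicate 1 shared, against 1321, 1270 and 1199 at 5 kb. Of 56 alternatives over 15 results, 17 could only leave the value in place: 14 left out a replicate from a covered share, where either of 2 values always lies within 1 SD of their mean, and 3 were the limit of 500 bp. Of the other 39, 20 moved the value and 19 did not, by a limit that depends on the kind of result. Some of these could move in only 1 direction, such as covered shares with fewer regions and counts at 3 kb. The tally is therefore no measure of robustness. Overlap between replicates, which has a test, was judged only by its direction and by p under 0.05, covered shares by 1 SD, score agreement and the share of combined regions by their 95% interval, and counts by a change of over 50% of the smaller count. Overlap, score agreement and the count of shared broad regions need both replicates, so they have no value without one. No paired analysis was possible because the inputs have no values of their own here, so no result is a test between immunoprecipitate and input. Depth is unknown, so its part in the differences between the lists was not assessed.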

Other observations

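All tests in this part were chosen after the lists had been seen, and only the comparison of chromosome 4 with runs of neighbouring regions had its prediction written before its result.

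Longer regions scored higher in each successive length class. Among regions under 2 kb, 0.859% ± 0.268 had a score of 1 or more (SD, n = 2), against 33.5% ± 0.407 from 2 to 2.5 kb, 76.8% ± 1.21 from 2.5 to 3 kb, 88.2% ± 1.26 from 3 to 5 kb and 97.3% ± 0.606 from 5 to 10 kb. All 284 regions of 10 kb or more in replicate 1 and all 261 in replicate 2 scored at least 1. In the combined list the 5 regions of highest score that neither replicate contained were 4 1349930 to 1350930 (3.17), 2L 21529369 to 21530369 (2.58), X 3184 to 4185 (2.07), 3L 8491408 to 8492408 (2.00) and U 6730993 to 6732159 (1.81). The first 4 were 1001 or 1002 bp long. The chromosome 4 region ends within 1 kb of the end of that sequence, which is 1351857 bp long.

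The 323 regions that only the combined list contained raise the question of what admitted them. By their length in the combined list, 42.4% of them (137) were at least as long as the shortest replicate region, 1301 bp. Their length in each replicate is unknown, so this does not settle whether a lower length limit in the combined list is the whole cause. The other 186 were shorter than any replicate region, so a limit on length may account for these. Weak enrichment that passes only with the replicates combined cannot be told apart from other causes by score. A first test found 95.05% of the 323 (307) in the lowest 25% of the combined list's scores, but so were 98.7% of the 319 combined regions found in a single replicate (315), so it was replaced. The median score of the 323 was higher than that of the 319, by 0.024 (two-sided permutation p = 0.00048), where a lower one had been predicted. Among those of at least 1301 bp, 137 against 296, the difference was -0.0084 (permutation p = 0.54). Over all of them the 323 were also shorter (median 1260 bp against 1703 bp), so length and score are mixed in that comparison and the explanation stays open. Regions found in a single replicate may also score low once combined, so weak enrichment need not give the 323 a lower median. The design has no group that gives a biological explanation, and none was tested.

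Regions on X were longer than on 2L, 2R, 3L and 3R. Averaged in windows of 1 Mb with at least 5 regions, the mean log2 length was higher on X by 0.17 in replicate 1 and by 0.16 in replicate 2, or 1.12-fold and 1.11-fold (22 windows on X against 96, of which 1 was the incomplete last window of 3R, two-sided permutation p = 6e-05 and 9e-05 with 100000 permutations). Leaving out any single X window kept the difference between 0.14 and 0.18. Within 5 equally filled bins of the score the difference was smaller, 0.096 in replicate 1 and 0.11 in replicate 2 (permutation p = 0.00049 and 7e-05). Scores may still differ between X and the other arms within a bin, so this cannot exclude higher scores on X as the whole cause. X was chosen after the lists had been seen, and no other arm was tested or adjusted for. The permutations treat neighbouring windows as independent, so these p-values may be too small. Windows of one library are not replicate animals. The number of X copies, which differs between male and female larvae, gene density and gene length on X were not tested and remain open.

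Regions on chromosome 4 ranked higher in replicate 2. Among the 4195 one-to-one pairs, the 54 on chromosome 4 had a mean score percentile of 34.7 in replicate 1 and 40.3 in replicate 2, and 42 of them moved up. Compared with arm regions of like rank, the shift was 5.82 percentile points. Runs of 54 neighbouring pairs on the other arms did not reach this shift. Of 3810 overlapping runs, 0 had a mean shift as large, the highest being 4.37. Chromosome 4 was chosen after the lists had been seen and the runs are not independent, so local variation is not excluded. A candidate explanation is a difference between the libraries in heterochromatic sequence, since the 45 pairs on the heterochromatin scaffolds also moved up, by 4.19 points, with 36 of 45 higher in replicate 2. Pairs within 1 Mb of the centromeric end of the assembled arm were also compared. They moved up by 6.34 points on 3L (6 pairs), 3.24 on 2R (19 pairs) and 2.56 on 2L (22 pairs). Those on 3R (39 pairs) and X (19 pairs) moved by -0.77 and -1.40, so the shift is not shared by all these ends. How much of each end is heterochromatic was not measured, so these values do not decide on the candidate explanation. Whether the immunoprecipitate or the input of a replicate differed cannot be read from these lists.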
